A study of Mus musculus with 25 samples.

How the data were processed

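Gene expression was measured in mouse Ep5 (EpRas) mammary tumour cells, a line that the labels give as C57BL/6, on 2 Affymetrix array types. The mouse exon arrays (13 samples) cover cells alone (5), cells cultured for 24 h with platelets at about 1000 platelets per cell (5), and cells joined with platelets only at lysis (3). The mouse gene arrays (12 samples) cover cells alone, with platelets, with the pellet of centrifuged platelets, and with the supernatant of that spin, called releasate in the labels (3 each). Groups were taken from the source names of the samples. On the gene arrays, 2 samples (alone 8 and platelets 9) carry a platelet tag that contradicts their group. They were kept in the group of the source name, and each count was repeated without them. The mean of the platelet list named below was 5.30 ± 0.02 (SD) over the 3 alone arrays and 5.55 ± 0.01 over the 3 platelet arrays. In platelet RNA both samples thus go with their source names.

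Per the submitters' processing notes, the exon arrays were processed with Partek 6.4 and RMA, and the gene arrays with Partek 6.5 and RMA. The deposited values are log2 probe set summaries. The labelling kits also differ between the array types per the labels. The options of background correction and of probe set summary are not recorded in the labels. The 2 tables were normalized separately, so no test crosses them. Array values carry no read depth, and the number of arrays limits the precision. The correlation between 2 arrays over all probe sets lay between 0.929 and 0.992 on the exon arrays and between 0.984 and 0.996 on the gene arrays.

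Of 44343 exon-array probe sets, 22781 have 1 gene symbol, 2085 several and 19477 none in the platform annotation. On the gene arrays, 21789 of 35556 have 1 symbol, 1621 several and 12146 none. Each gene was represented by the probe set with 1 symbol and the highest mean over all arrays of its table, which gave 18997 genes on the exon arrays and 19938 on the gene arrays. Of these, 2076 and 999 had several probe sets to choose from. Symbols follow that annotation, which can be old, and probe sets without a single symbol were only counted.

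Differences between groups were estimated with limma 3.58.1 in R 4.3.3, with linear models and empirical Bayes moderation. Each table was fitted on its own with all of its groups, so that the groups share an estimate of the spread. Adjusted p values are Benjamini-Hochberg values over all genes of a table, and a gene counts as changed at an adjusted p under 0.05. Differences are given as log2 values with their standard error (SE), and levels as mean log2 values with their standard deviation (SD). Groups share replicate numbers in the labels. Deviations of same-numbered gene-array samples from their group means had correlations of 0.287 to 0.442 between alone and platelets and of 0.292 to 0.381 between alone and releasate, all 3 pairs over 0.1. The numbers were taken to pair the samples in these 2 comparisons, and so between platelets and releasate (0.07 to 0.303), on the correlations and not on a label, and the fit with the number as a block is given where a call or count changes. In the other comparisons not all pairs were over 0.1, or fewer than 3 pairs exist. Of the 3 pellet pairs, 2 were over 0.1 with alone and 1 with releasate. The same numbers run over the pellet samples, so fits with the block are also given for pellet against these 2 groups. The reading of pairs per comparison was chosen after both fits were seen. The labels do not say whether samples are separate cultures, so the p values measure the spread between these samples.

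The comparisons, their design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 18 lists are epithelial junction and keratin, mesenchymal, EMT (epithelial-mesenchymal transition) transcription factors, TGF-beta response, NF-kappaB response, matrix proteolysis, growth factor and ERK response, YAP and TEAD targets, proliferation, hypoxia and glycolysis, cholesterol synthesis, interferon response, endoplasmic reticulum and amino acid stress, oxidative stress and haem response, mammary secretory, platelet, erythroid, and leukocyte. Lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and, as alternatives, with a correlation estimated per list and with fry. Fry asks whether a list differs between groups at all, without reference to the other genes. Camera p values were adjusted over the 18 lists within a comparison. Counts of members were also made with p values adjusted over the list alone. The mean of the platelet, erythroid and leukocyte lists per array, and of other lists where given, was compared with exact two-sided permutation tests.

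Named genes on the exon arrays are the 10 largest rises and 10 largest falls among genes past both controls in the same direction without overlap of the groups, and up to 10 rises and 5 falls between cells mixed at lysis and cells alone. On the gene arrays they are the 10 largest rises and falls with platelets, and the 5 largest of each in the other comparisons, without overlap of the groups. For each list, up to 4 members past the threshold with the largest differences are named. Where none passed, 2 values are given at most. The genes Cdh1, Snai1, Vim, Fn1, Mmp9, Ccl2, Tgfb1, Nfkbia, Pf4 and Ppbp were followed in every comparison whatever their value, and 1 more gene of that rule is not analysed here.

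The fit was tested on simulated data with 200 changed genes placed on the spread of the real arrays. For platelets against alone on the exon arrays, 46.3% of genes changed by 0.5 log2, 86.6% of those changed by 1 and 97.0% of those changed by 2 were recovered, with 5 false calls among 158. For platelets against alone on the gene arrays the shares were 68.7%, 91.0% and 98.5%, with 14 false calls among 186.

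The alternatives tried were moderation with an intensity trend and robust to outlying genes, removal of the genes under the 30th percentile of the mean, every probe set with a symbol, equal array medians, quantile normalization applied again, the replicate number as a block, a log2 difference of at least 1, fits with only the compared groups, each array left out, the gene arrays without the 2 conflicting tags, and the serial numbers of the titles as a block. Chosen after the values were seen were limma's array weights, fits within and blocked by exon arrays numbered 1 to 3 and 4 to 6, a fit without the 2 arrays of alone and the 2 of platelets that correlated least with their exon-array group, and both scalings for lists and named genes. Scripts ran under Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.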

Results

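The data are log2 expression values of mouse Ep5 (EpRas) mammary tumour cells, on 13 exon arrays and 12 gene arrays. The exon arrays hold cells alone (n = 5), cells after 24 h with platelets (n = 5), and cells that met platelets only at lysis (n = 3), a control for RNA that platelets carry. The gene arrays hold cells alone, with whole platelets, with the platelet pellet, and with the releasate (n = 3 each). Array medians over all probe sets lay between 3.62 and 3.90 on the exon arrays and between 5.56 and 5.63 on the gene arrays.

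Exon arrays addressed what a day with platelets does to the RNA of the tumour cells, beyond the RNA that platelets bring. Mmp9, a gelatinase that cleaves basement membrane collagen (probe set 6883125), rose from a log2 level of 3.92 ± 0.30 (SD, n = 5) alone to 9.75 ± 0.48 (n = 5) with platelets, and was 4.20 ± 0.36 (n = 3) in cells mixed at lysis. The difference in signal was 5.84 ± 0.23 (SE), by limma with an adjusted p of 9.38e-08. No signal was tested against background, and Mmp9 alone lies near the array medians. Where background sets the low value, as it can for Mmp9 or C1qtnf1, a difference understates the change, and its rank is a rank of signal. The cathepsin gene Ctsw (6871117) rose by 4.95 ± 0.21 and the matricellular gene Ccn4 by 4.48 ± 0.21. The lymphatic growth factor Vegfc rose by 3.55 ± 0.30, the adhesion molecule Ncam1 by 2.89 ± 0.18, the secreted chaperone Clu by 2.84 ± 0.14, the Notch ligand Jag1 by 2.44 ± 0.21 and the ectonucleotidase Nt5e by 2.34 ± 0.29. C1qtnf1 (from 3.84 ± 0.21 to 6.84 ± 0.26, SD) and the sulfotransferase Chst2 (by 2.93 ± 0.36) completed the 10 largest rises.

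Among the falls with platelets, the aldehyde dehydrogenase Aldh3a1 changed most, at −3.69 ± 0.39 against cells alone, from a level of 9.62 ± 0.72 to 5.93 ± 0.77. Lrrc26 (−3.30 ± 0.29), Them6 (−3.25 ± 0.49) and Bpifb4 (−3.19 ± 0.26) followed. The kinase gene Sgk2 changed by −2.97 ± 0.46 and Id2, an inhibitor of basic helix-loop-helix factors, by −2.95 ± 0.39. Gpr146, Rom1, Atp13a4 and Mcpt8 made up the rest of the 10, between −2.86 and −2.76. The adjusted p of these 20 genes lay at or under 0.00211 against cells alone and at or under 0.0068 against cells mixed at lysis.

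**Figure D1:**
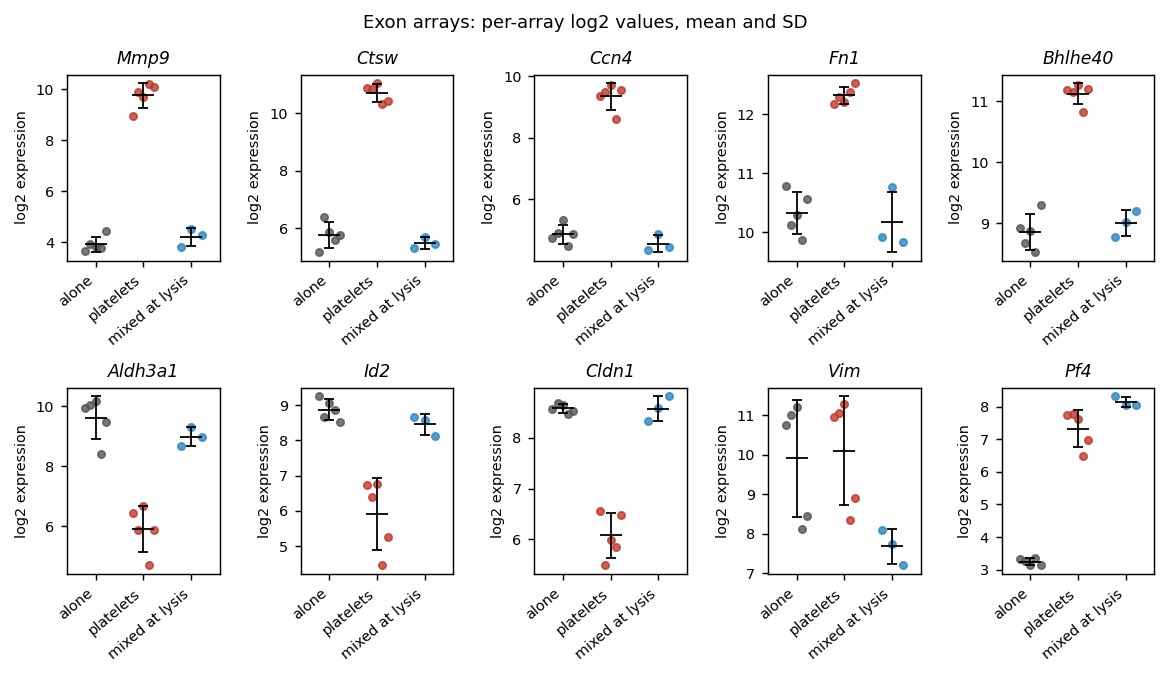
Log2 expression of 10 genes on the exon arrays, where each point is 1 array, the bar the mean and the whisker the SD, for cells alone (n = 5), with platelets (n = 5) and mixed at lysis (n = 3). Mmp9 lies at 9.75 with platelets against 3.92 alone and 4.20 mixed at lysis, while Pf4 is at 7.32 with platelets and 8.15 mixed at lysis.

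With platelets, 864 of 18997 genes differed from cells alone, 394 higher and 470 lower, and 301 of them by at least 1 log2. At an unadjusted p under 0.05 there were 2537, where 950 would be expected with no difference. Against cells mixed at lysis, 699 genes differed, 292 higher and 407 lower. In both comparisons and in the same direction, 570 genes passed, 241 higher and 329 lower. Quantile normalization applied again turned the balance of directions, to 452 higher and 361 lower against alone, 357 and 296 against mixed at lysis, and 287 and 240 past both. Against mixed at lysis the balance also turned with array weights (2628 and 1774) and without alone 1, alone 5, platelets 4 and platelets 5 (1192 and 920). The count against cells mixed at lysis was 464 without mixed at lysis 5 and 397 without mixed at lysis 6, and the count past both was 379 without the latter. Arrays numbered 1 to 3 stood apart from the others in some genes, such as Vim. Within numbers 1 to 3, 922 genes differed between platelets and alone. With only numbers 4 and 5 (n = 2 each) 42 did. The sets of numbers as a block gave 1076 genes against alone, 551 against mixed at lysis and 512 past both. The replicate number as a block gave 1326, 472 and 461.

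Genes of epithelial junctions and keratins moved down as a list. Of 38 measured, 9 fell, 3 rose and 26 did not pass (11 and 4 adjusted over the list alone). The tight junction gene Cldn1 fell by 2.50 ± 0.18 on the log2 scale, the polarity gene Crb3 by 1.76 ± 0.18, the epithelial transcription factor Elf3 by 1.40 ± 0.26 and Mal2 by 1.27 ± 0.24. The list passed camera against cells alone (adjusted p = 0.000295, and 0.0277 with an estimated correlation) and against cells mixed at lysis (adjusted p = 1.89e-06, and 0.0266 with an estimated correlation). The cadherin gene Cdh1 did not pass, with a difference of −0.15 ± 0.24 against alone (adjusted p = 0.941) and −0.02 ± 0.28 against mixed at lysis.

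The mesenchymal list moved up, with 6 of 31 members higher, 0 lower and 25 not past the threshold (8 and 1 adjusted over the list alone). The fibronectin receptor subunit Itga5 rose by 2.00 ± 0.21, fibronectin itself (Fn1) by 1.99 ± 0.20, tenascin (Tnc) by 1.86 ± 0.22 and the integrin Itgb3, which is also on the platelet list, by 1.43 ± 0.17. Camera gave an adjusted p of 4.81e-06 (0.0194 with an estimated correlation) against alone and 2.35e-05 (0.0321) against mixed at lysis. Vim, the mesenchymal intermediate filament, differed by 0.20 ± 0.74 from cells alone (adjusted p = 0.988) and had an SD of 1.49 among the arrays of cells alone. Of 17 EMT transcription factors, 2 rose against alone (3 adjusted over the list alone). Snai1 did by 1.46 ± 0.36 (adjusted p = 0.0394) and Zeb1 by 0.60 ± 0.12. Snai1 did not pass against cells mixed at lysis (0.66 ± 0.42, adjusted p = 0.554). All arrays mixed at lysis are numbered 4 to 6, and Snai1 was 1.07 lower in numbers 1 to 3 than in 4 and 5. With the sets of numbers as a block, chosen after the values were seen, its difference from mixed at lysis was 1.30 (adjusted p = 0.0282). Its difference from alone in that fit was 1.46 (adjusted p = 0.00158). That list had an adjusted p of 0.0463 by camera against alone, and an adjusted p = 0.0796 with an estimated correlation. The Snai1 call against alone was lost in each fit without 1 of the arrays of the 2 groups, except alone 5, with adjusted p values of 0.0506 (without platelets 3) to 0.0997 (without alone 2).

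TGF-beta response genes rose together. Of 29 measured, 11 rose and 0 fell against cells alone (13 and 0 adjusted over the list alone), with a mean difference of 0.57. Bhlhe40, a circadian and hypoxia-linked repressor, rose by 2.26 ± 0.14, the peptide hormone Edn1 by 1.96 ± 0.30, the protease inhibitor Timp3 by 1.69 ± 0.20 and the matricellular gene Ccn2 by 1.45 ± 0.19. Camera gave adjusted p = 6.95e-12 against alone and 1.51e-06 against mixed at lysis, which became 0.0194 and 0.0346 with an estimated correlation. The ligand Tgfb1 differed by 0.30 ± 0.43 (adjusted p = 0.919). Among 20 YAP and TEAD targets, 5 rose and 0 fell (6 and 1 adjusted over the list alone), with Nt5e, Ccn2, Ccn1 (1.10 ± 0.24) and Nuak2 (0.84 ± 0.12) the largest. They passed camera against alone (adjusted p = 0.00641, and 0.0277 with an estimated correlation) but not against mixed at lysis (adjusted p = 0.0842). Ccn1 lost its call without alone 3 (adjusted p = 0.0525).

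NF-kappaB response genes rose in 6 cases and fell in 2 of 33 (10 and 3 adjusted over the list alone). The inhibitor gene Nfkbie and Nfkbiz, which encodes a nuclear protein of the same family, rose by 1.15 ± 0.12 and 1.12 ± 0.16, the macrophage growth factor Csf1 by 0.86 ± 0.19, and Tnfaip2 fell by 0.71 ± 0.11. Nfkbia rose by 0.36 ± 0.09 (adjusted p = 0.0412, and 0.103 with equal array medians). The chemokine Ccl2 was 2.36 ± 0.63 higher than in cells alone without passing (adjusted p = 0.0577), and passed without alone 3 (adjusted p = 0.0379) or without platelets 4 (0.00195). Against cells mixed at lysis Ccl2 rose by 3.42 ± 0.73 (adjusted p = 0.0205), a call lost without platelets 1 (0.0546), 2 (0.0525) or 3 (0.0505) and without mixed at lysis 4 (0.0635), 5 (0.0559) or 6 (0.104). With the sets of numbers as a block, Ccl2 was 2.36 higher than alone (adjusted p = 0.0088) and 2.41 higher than mixed at lysis (adjusted p = 0.0534). The list had an adjusted p of 0.00599 against alone, an adjusted p = 0.0703 with an estimated correlation, and 0.0797 against mixed at lysis. The call of Csf1 was lost without platelets 1 (adjusted p = 0.0541). That of Nfkbia was lost without alone 1 (0.0797), 2 (0.063), 3 (0.102) or 5 (0.0905), and without platelets 1 (0.112), 2 (0.083), 3 (0.102) or 4 (0.0552).

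Genes of matrix proteolysis moved both ways, with 6 of 31 higher and 3 lower (7 and 5 adjusted over the list alone). The collagenase Mmp13 rose by 1.97 ± 0.34 and the stromelysin Mmp10 by 1.82 ± 0.28, while the stromelysin Mmp3 changed by −2.76 ± 0.32. As a list they did not pass camera against alone (adjusted p = 0.0588). Of 28 growth factor and ERK response genes, 6 fell and 3 rose (11 and 3 adjusted over the list alone). The epidermal growth factor family members Epgn and Ereg fell by 1.12 ± 0.26 and 0.99 ± 0.20, while Fos rose by 1.24 ± 0.13 and the angiogenic factor Vegfa by 1.11 ± 0.12. Their camera call against alone (adjusted p = 0.00511) had an adjusted p = 0.102 with an estimated correlation. Against mixed at lysis the list was lower at an adjusted p of 1.44e-05 (0.0346 with an estimated correlation). Epgn lost its call against alone without alone 2 (adjusted p = 0.0605), 4 (0.0685) or 5 (0.0543), and without platelets 1 (0.0686), 2 (0.0701), 4 (0.062) or 5 (0.064).

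Hypoxia and glycolysis genes fell. Of 25 measured, 10 were lower and 0 higher than in cells alone (16 and 2 adjusted over the list alone), with a mean difference of −0.47. Adrenomedullin (Adm) fell by 1.38 ± 0.30, the carbonic anhydrase Car9 by 1.17 ± 0.13, the mitophagy receptor Bnip3 by 1.14 ± 0.24 and the pyruvate dehydrogenase kinase Pdk1 by 1.07 ± 0.18. Camera gave adjusted p = 1.39e-10 against alone (0.0277 with an estimated correlation) and 1.56e-10 against mixed at lysis (0.0346). Adm missed the threshold after quantile normalization (adjusted p = 0.0925). Oxidative stress and haem response genes were lower in 3 and higher in 1 of 15 (7 and 1 adjusted over the list alone). The detoxifying enzymes Gstm1, Nqo1 and Gsta4 fell by 1.36 ± 0.27, 0.87 ± 0.20 and 0.87 ± 0.14, and the haem oxygenase Hmox1 rose by 0.82 ± 0.20. Hmox1 lost its call with equal array medians (adjusted p = 0.0561), without alone 1 (0.0903), 2 (0.0628), 3 (0.0893) or 5 (0.0896), and without platelets 1 (0.107), 2 (0.108), 3 (0.102) or 5 (0.0559). Nqo1 lost its call without alone 2 (0.0642), 3 (0.0619) or 5 (0.051), and without platelets 1 (0.0548), 4 (0.0502) or 5 (0.0578). That list passed camera against alone (adjusted p = 0.00015) with an adjusted p = 0.0526 with an estimated correlation, and against mixed at lysis (adjusted p = 0.000257) with an adjusted p = 0.0746 with an estimated correlation.

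Mammary secretory genes fell in 3 of 15 cases and rose in 0 (3 and 1 adjusted over the list alone): the milk fat protein Btn1a1 by 1.73 ± 0.14, Xdh by 1.48 ± 0.25 and the casein Csn3 by 1.15 ± 0.12. As a list they did not pass (adjusted p = 0.121). Of 28 proliferation genes 0 passed, and the values furthest from 0 were Birc5 at −0.63 ± 0.19 (adjusted p = 0.109) and Tk1 at −0.34 ± 0.13. None of the 19 cholesterol synthesis genes passed, with values of 0.30 ± 0.11 for Hsd17b7 and −0.26 ± 0.29 for Insig1. In the interferon list 1 of 22 fell, Bst2 (−0.59 ± 0.15), and in the endoplasmic reticulum and amino acid stress list 1 of 22 fell, the serine synthesis enzyme Phgdh (−0.38 ± 0.10). Adjusted over the list alone, these 4 lists gave 0, 0, 1 and 1 lower genes and 0 higher ones. Their camera adjusted p values were 0.533, 0.835, 0.354 and 0.129, and the proliferation list had a median of 0.01 beside a mean of −0.05. Bst2 (adjusted p = 0.0455) and Phgdh (0.0498) lost their calls in all but 1 of the fits that left out 1 array of either group, at adjusted p values of 0.0615 to 0.0957 and 0.0599 to 0.111. The exception was alone 5 for both. With equal array medians they had adjusted p values of 0.13 and 0.259, and Bst2 had 0.204 after quantile normalization.

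**Figure D2:**
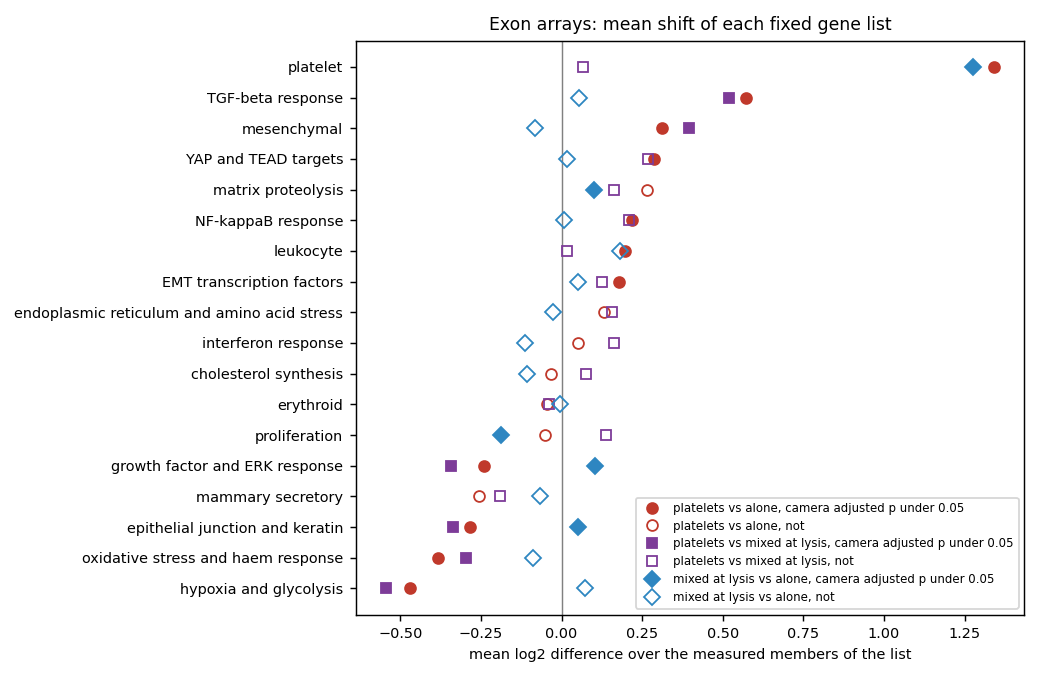
Mean log2 difference over the measured members of each of the 18 gene lists on the exon arrays, with filled symbols for a camera adjusted p under 0.05. For platelets minus alone, platelets minus mixed at lysis and mixed at lysis minus alone, the platelet list lies at 1.34, 0.07 and 1.28, and the TGF-beta response list at 0.57, 0.52 and 0.05.

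Cells mixed with platelets at lysis show which RNAs the platelets carried. The chemokine gene Pf4, a platelet alpha-granule product, rose from 3.25 ± 0.11 (SD, n = 5) to 8.15 ± 0.15 (n = 3), a difference of 4.90 ± 0.25 (SE, adjusted p = 2.04e-06). Alone, Pf4 and Rgs18 lie under the medians of all arrays, where background can set the value and a difference then understates the change. Ppbp rose by 4.21 ± 0.55, Rgs18 from 3.28 ± 0.11 to 7.28 ± 0.40 (SD), the lipoxygenase-activating protein Alox5ap by 3.13 ± 0.43 and the podoplanin receptor Clec1b by 3.04 ± 0.45. Cd226, Srgn, Gng11 and Nrgn were the other genes that rose, by 2.93 ± 0.38, 2.89 ± 0.38, 1.87 ± 0.27 and 1.43 ± 0.15. In all 9 genes passed, 9 higher and 0 lower, with 748 at an unadjusted p under 0.05 where 950 would be expected. The count rested on single arrays: it was 3 without alone 1, without alone 2 or without alone 3, 4 without alone 5, 2 without mixed at lysis 5 and 1 without mixed at lysis 6. Only Pf4 passed in each of these fits. Nrgn lost its call without mixed at lysis 6 (adjusted p = 0.0549), and Rgs18 without mixed at lysis 5 (0.0726) or 6 (0.0549). Clec1b and Gng11 lost theirs with equal array medians (0.0558 and 0.0564) and after quantile normalization (0.0869 and 0.155). Beside the count of 0 lower genes, limma's array weights gave 93 higher and 138 lower.

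On the platelet list 6 of 27 members rose and 0 fell between mixed at lysis and alone (12 and 0 adjusted over the list alone), with a camera adjusted p of 3.82e-33 (0.037 with an estimated correlation). In the cultures with platelets 13 rose and 0 fell against alone (20 and 0 adjusted over the list alone; adjusted p = 3.2e-23, and 0.0277 with an estimated correlation). The list mean per array was 3.61 ± 0.04 (SD, n = 5) alone, 4.96 ± 0.56 (n = 5) with platelets and 4.89 ± 0.16 (n = 3) mixed at lysis. Exact two-sided permutation tests gave p = 0.00794 for platelets against alone, 0.0179 for mixed at lysis against alone and 0.911 for platelets against mixed at lysis. The first 2 are the smallest that those numbers of arrays can give. The last averages over arrays that part by number: platelets 1 to 3 lay above every mixed at lysis array (4.76, 5.06 and 4.85), and platelets 4 and 5 (4.21 and 4.57) below. Against alone the list rose by 1.73 in numbers 1 to 3 and by 0.75 in numbers 4 and 5. With the sets of numbers as a block, Pf4 was 1.12 lower with platelets than mixed at lysis (adjusted p = 0.0202). Erythroid genes had a mean difference of −0.05 with platelets (exact permutation p = 0.135), and 1 of 13 fell, the iron transporter Slc25a37 (−0.64 ± 0.09). Their median was 0.00 and their camera adjusted p 0.533. Leukocyte genes were 0.20 higher in the mean (exact permutation p = 0.00794), with 2 of 23 higher and 0 lower (3 and 0 adjusted over the list alone). These were Laptm5 (2.33 ± 0.45) and Csf1r (0.37 ± 0.08). The leukocyte list passed camera against alone (adjusted p = 0.0217), with an adjusted p = 0.161 with an estimated correlation. Csf1r lost its call without alone 2 (adjusted p = 0.0562).

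Other lists moved less between mixed at lysis and alone, and 0 members of any passed in limma over all genes. By camera the proliferation list was lower (mean −0.19, adjusted p = 0.000424) and the growth factor and ERK response list (0.10, 0.00184), the matrix proteolysis list (0.10, 0.0135) and the epithelial list (0.05, 0.0314) were higher. With an estimated correlation these were adjusted p = 0.455, 0.185, 0.185 and 0.227. Egr3, an ERK target, had the largest value of its list at 0.86 ± 0.19 (adjusted p = 0.49). For the leukocyte list the median was −0.01 and the mean 0.18, and for the mesenchymal list the camera direction was up at a mean of −0.08 (adjusted p = 0.907).

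The gene arrays repeated platelets against alone in other samples and added the pellet and the releasate, to ask which part of the platelet the cells respond to. They hold no cells mixed at lysis, so RNA that platelets carry is not told apart from a response of the cells. With whole platelets, the basal keratin Krt14 rose by 2.21 ± 0.43 (SE, n = 3 per group, adjusted p = 0.0461, and 0.0502 with equal array medians), Ncam1 by 2.17 ± 0.36, Clu by 2.16 ± 0.34, Ctsw by 2.08 ± 0.32 and Ccn4 by 1.94 ± 0.27. Pf4 (1.86 ± 0.25), Adamtsl3 (1.53 ± 0.25), Jag1 (1.41 ± 0.25), the adhesion molecule Mcam (1.34 ± 0.24) and Plek2 (1.33 ± 0.20) were the next. Fer1l6 changed by −2.40 ± 0.43 and the kallikreins Klk6 and Klk10 by −2.02 ± 0.34 and −1.99 ± 0.29. Bpifb4, the granzyme Gzme, Atp13a4, Tns4, Cavin2, Rhpn2 and Nptx1 also fell, with differences between −1.61 and −1.17. Mmp9 was 2.10 ± 0.43 higher without passing (adjusted p = 0.0583), and passed with the replicate number as a block (adjusted p = 0.00563).

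**Figure D3:**
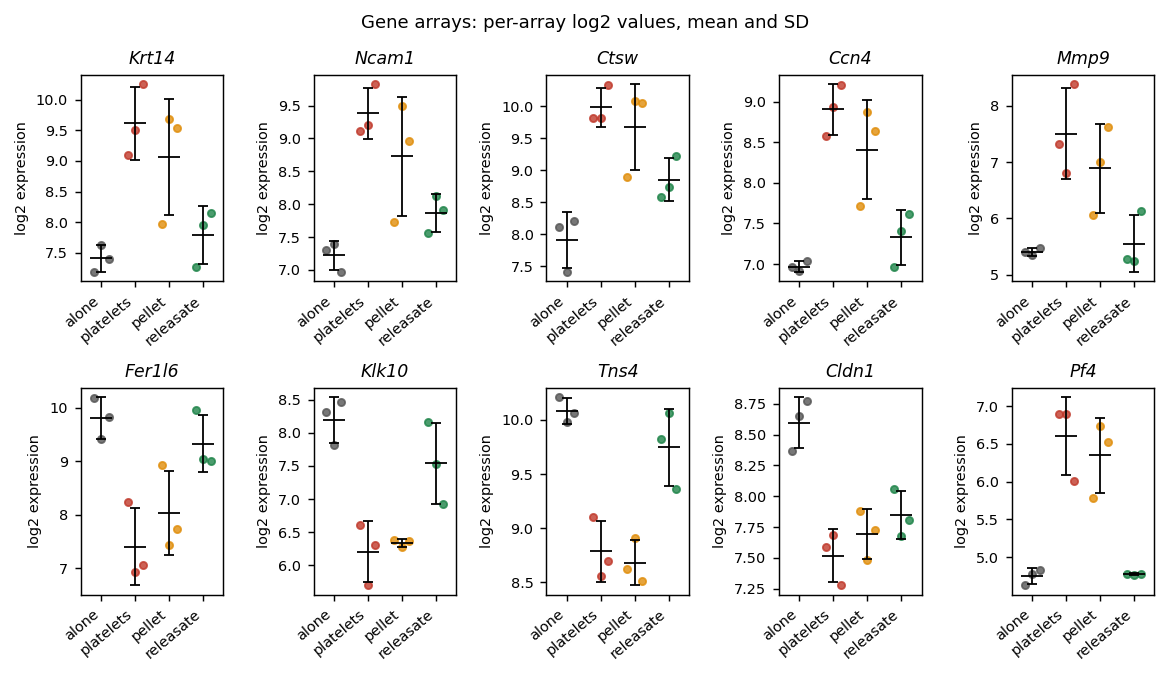
Log2 expression of 10 genes on the gene arrays, where each point is 1 array, the bar the mean and the whisker the SD, for cells alone, with platelets, with the pellet and with the releasate (n = 3 each). Ctsw lies at 7.91 alone, 9.99 with platelets, 9.68 with the pellet and 8.85 with the releasate.

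In total 133 of 19938 genes differed with platelets on the gene arrays, 82 higher and 51 lower, with 1916 at an unadjusted p under 0.05 where 997 would be expected. The count was 21 without alone 9, 41 without alone 7, 51 without platelets 8, 66 without platelets 9 and 75 without alone 8. Without both arrays of conflicting tags it was 30, and with the replicate number as a block 454. Of 45 named gene-array calls over all comparisons, 6 held without each array in fits without the block, and these include Cavin2, Nt5e and Clec1b here. Few members of the lists passed. The tight junction gene Cldn1 fell by 1.07 ± 0.15, and the matrix gene Postn (0.63 ± 0.11), Nt5e (1.08 ± 0.11), Pf4 and Clec1b (0.74 ± 0.06) rose. For TGF-beta response genes 0 passed over all genes and 2 higher and 1 lower adjusted over the list alone. Camera called the hypoxia and glycolysis list lower (mean −0.29, adjusted p = 7.34e-05), with the growth factor and ERK response (−0.21, 0.00134) and mammary secretory (−0.26, 0.0148) lists. It called the TGF-beta response (0.24, 0.0029), platelet (0.24, 0.0016), mesenchymal (0.15, 0.016) and interferon (0.18, 0.0148) lists higher. None of the 7 held with an estimated correlation, at an adjusted p = 0.119 for the platelet list and an adjusted p = 0.233 for the others. Values of the followed genes were 0.01 ± 0.13 for Cdh1, 0.93 ± 0.68 for Vim, 0.59 ± 0.15 for Fn1 and 0.19 ± 0.13 for Snai1, all without passing. With the replicate number as a block Vim passed (0.93, adjusted p = 0.00663).

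With the pellet, Ctsw (1.77 ± 0.32), Pf4 (1.60 ± 0.25), Ccn4 (1.44 ± 0.27), Fkbp7 (1.18 ± 0.18) and Vegfc (1.15 ± 0.15) rose the most. Klk10 (−1.86 ± 0.29), Bpifb4 (−1.50 ± 0.28), Tns4 (−1.40 ± 0.18), Rhpn2 (−1.12 ± 0.16) and Nptx1 (−1.05 ± 0.19) fell the most. With equal array medians Ctsw (adjusted p = 0.0541), Ccn4 (0.0573), Bpifb4 (0.0514) and Nptx1 (0.053) lost their calls. Cldn1 also fell, by 0.90 ± 0.15, and Nt5e rose by 0.92 ± 0.11. Vim (0.82, adjusted p = 0.0157) and Mmp9 (1.48, 0.032) passed with the replicate number as a block, which gave 359 genes. Without the block they did not pass, and 83 genes differed from cells alone, 47 higher and 36 lower, with 1921 at an unadjusted p under 0.05. The count moved to 8 without alone 9, 13 without pellet 8 or without pellet 9, 16 without alone 7, 41 without alone 8 and 133 without pellet 7. By camera the hypoxia (mean −0.36, adjusted p = 4.79e-08), epithelial (−0.15, 0.00108), ERK (−0.21, 0.00108) and mammary (−0.23, 0.0185) lists were lower. The platelet (0.21, 0.00179) and mesenchymal (0.11, 0.0399) lists were higher. None held with an estimated correlation (adjusted p = 0.138 to 0.556). Camera with the block, at the preset correlation, also called the TGF-beta response (mean 0.134, adjusted p = 0.0164) and interferon (0.137, 0.0112) lists. Exact permutation tests of these list means, without the block, gave p = 0.3 and 0.2. Platelets and pellet shared 38 higher genes (0.193 expected for independent lists) and 29 lower ones (0.0921). Across genes their differences from alone had r = 0.791, where unchanged groups against the same controls gave 0.499, and a covariance of 0.0225 where unchanged groups gave 0.0059. Part of the excess may come from the shared controls, and genes are not independent replicates. The unchanged groups were simulated as independent samples, without any pairing by number.

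With the releasate 0 genes passed in limma, with 563 at an unadjusted p under 0.05 where 997 would be expected. The count was also 0 under every other setting run, array weights and robust moderation included. The values of Cldn1 (−0.75 ± 0.15), Nt5e (0.30 ± 0.11), Dusp1 (−0.87 ± 0.24), Mmp9 (0.14 ± 0.43) and Pf4 (0.03 ± 0.25) had an adjusted p of 1. Camera called the growth factor and ERK response list (mean −0.13, adjusted p = 0.000185) and the epithelial list (−0.06, 0.0221) lower and the proliferation list (0.075, 0.0221) higher. With an estimated correlation these were adjusted p = 0.464, 0.7 and 0.7. With the replicate number as a block, camera also called the NF-kappaB (adjusted p = 0.0144), matrix proteolysis (0.0296) and hypoxia (0.009) lists lower. Without the block but with an estimated correlation these had an adjusted p = 0.406, 0.7 and 0.7. The releasate and platelet effects had r = 0.583 across genes beside 0.498 for unchanged groups, with covariances of 0.0094 and 0.0059. The simulation of unchanged groups left out the pairing by number that was taken to hold here.

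Direct tests compared the platelet fractions. Between whole platelets and pellet 0 passed in limma (503 at an unadjusted p under 0.05), also under every other setting run. Whole platelets and releasate differed in 9 genes, 7 higher and 2 lower with platelets (1320 at an unadjusted p under 0.05). Pf4 (1.83 ± 0.25), Cd226 (0.95 ± 0.11), Nt5e (0.77 ± 0.11), Clec1b (0.72 ± 0.06) and Chst2 (0.61 ± 0.07) were higher. Of these, Pf4, Cd226 and Clec1b also rose on the exon arrays in cells mixed at lysis, where platelets bring RNA. Rhpn2 (−1.12 ± 0.16) and Lat2 (−0.63 ± 0.06) were lower. The count was 4 without releasate 7 or without releasate 8, 5 without platelets 7, and 0 with only the compared groups in the fit. With the replicate number as a block it was 98, and Mmp9 (1.96, adjusted p = 0.0213) and Ppbp (2.54, 0.0271) passed. Camera with the block, at the preset correlation, called the mesenchymal (mean 0.109, adjusted p = 0.0439) and mammary secretory (−0.191, 0.0408) lists. Exact permutation tests of these list means, without the block, gave p = 0.1 and 0.2. The smallest p that 3 against 3 arrays allow is 0.1, so these tests could not pass and do not decide. With equal array medians Pf4 (0.0539), Nt5e (0.0539) and Rhpn2 (0.0586) lost their calls. Pellet and releasate differed in 1 gene, the adaptor Lat2 (−0.57 ± 0.06, adjusted p = 0.042), and in 0 genes in each fit that left out 1 of their 6 arrays and with equal array medians (adjusted p = 0.0963), with 1139 at an unadjusted p under 0.05. The replicate number as a block gave 44 genes between pellet and releasate, and Pf4 passed (1.57, adjusted p = 0.0476). Camera with the block, at the preset correlation, called the epithelial (mean −0.088, adjusted p = 0.0311) and mammary secretory (−0.158, 0.0222) lists. It also called the TGF-beta response (0.106, 0.0228) and interferon (0.082, 0.0148) lists. Exact permutation tests of these list means, without the block, gave p = 0.2 to 0.4, and again 0.1 was the smallest p they could give. The departure of whole platelets from the sum of pellet and releasate effects passed in 0 genes (562 at an unadjusted p under 0.05), also under every other setting run. Its largest followed value was Ppbp at 1.49 ± 0.60.

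Lists separated the fractions at the preset correlation. Against releasate, the platelet list was higher with whole platelets (mean 0.28, adjusted p = 0.000338, and 0.0489 with an estimated correlation) and with pellet (0.245, 0.000123, and 0.0445 with an estimated correlation). Hypoxia and glycolysis genes were lower than with releasate for whole platelets (−0.21, adjusted p = 0.00443) and for pellet (−0.27, 8.22e-06), with 0 members past the threshold. With an estimated correlation these were adjusted p = 0.455 and 0.519. Whole platelets were higher in the TGF-beta response list (0.21, 0.00426) and the interferon list (0.12, 0.0112), each with an adjusted p = 0.379 with an estimated correlation. Pellet was lower in the proliferation list (−0.12, 0.00858), with an adjusted p = 0.625 with an estimated correlation. Between whole platelets and pellet, the epithelial and cholesterol synthesis lists were higher by 0.10 and 0.09 (both adjusted p = 0.0481, and 0.601 with an estimated correlation). The sum test called the epithelial list (0.16, 0.000477), the ERK (0.14, 0.0159), hypoxia (0.16, 0.0159) and YAP (0.14, 0.0279) lists, each with an adjusted p = 0.643 with an estimated correlation. The platelet list mean per array was 5.30 ± 0.02 (SD, n = 3) alone, 5.55 ± 0.01 with platelets, 5.52 ± 0.02 with pellet and 5.27 ± 0.01 with releasate. Each pair of groups had an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow.

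Genes called for whole platelets mostly had the same direction on both array types. Across 17491 genes present on both, the platelet differences had r = 0.656 and a rank correlation of 0.414, and 10648 (60.9%) had the same direction. Of 559 genes past both controls on the exon arrays, 545 (97.5%) had the same direction on the gene arrays, with a median size of 0.93 on the exon and 0.36 on the gene arrays. Of 125 genes called on the gene arrays, 124 had the same direction on the exon arrays. Their median sizes were 1.01 on the exon and 0.66 on the gene arrays. Both array types called 53 genes higher (1.71 expected for independent lists) and 39 lower (1.23). Ncam1, Clu, Ctsw, Ccn4 and Jag1 were among the 10 largest rises and Bpifb4 and Atp13a4 among the 10 largest falls on both. By camera at the preset correlation, the TGF-beta, mesenchymal, platelet, hypoxia and ERK lists were called on both. The interferon and mammary secretory lists were called on the gene arrays only. The interferon mean was 0.177 there and 0.051 on the exon arrays. The mammary secretory mean was of like size on both, −0.261 on the gene and −0.257 on the exon arrays. Exact permutation tests of that mean gave p = 0.1 and 0.00794, so its calls by camera do not show a difference between the array types. The NF-kappaB, YAP, oxidative stress, epithelial, EMT and leukocyte lists were called on the exon arrays only. The means of these lists were 0.218, 0.286, −0.382, −0.285, 0.179 and 0.196 there, and −0.074, 0.022, 0.004, −0.053, 0.039 and −0.006 on the gene arrays. No test crosses the tables, and genes are not independent replicates.

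**Figure D4:**
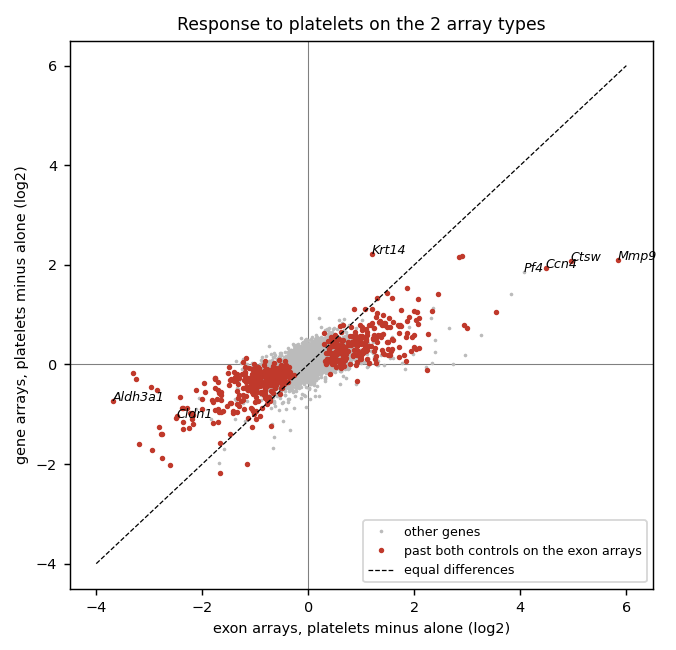
Difference between platelets and alone (log2) on the exon arrays (x axis) and the gene arrays (y axis) for 17491 genes. Red points passed both controls on the exon arrays, and 545 of these 559 have the same direction on both axes, at a smaller size on the gene arrays.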

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

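The tests of cultures shared by a number, of fewer arrays, of RNA brought by the platelets and of leukocytes were chosen only after the result was seen, as were the fits within numbers.

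Vim lay apart between exon arrays numbered 1 to 3 and those numbered 4 and 5, by 2.59 log2 across alone and platelets (adjusted p = 0.000199), and 177 genes differed between these sets. Scaling of the arrays is excluded, as the gap was 2.56 after quantile normalization. Fibroblast-like cells rich in collagen and matrix RNA are excluded as well, since 11 such genes had a median gap of −0.12 (−0.41 to 0.07). The test covers these genes only. Among other members of the mesenchymal and EMT lists, Cdh2 (1.23), Zeb2 (0.52) and Foxc1 (0.44) were higher in numbers 1 to 3, as Vim was. Snai1 (−1.07) was lower there. Cultures or passages shared by a number remain a candidate explanation: on the gene arrays, number 8 had the highest Vim in 4 of 4 groups and number 9 the lowest. No other explanation was tested. The platelet effect differed between the sets in 0 genes, with 1356 at an unadjusted p under 0.05 where 950 would be expected. A difference in the platelet effect between the sets is thus not excluded.

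Platelets changed 133 genes on the gene arrays against 864 on the exon arrays, and 454 against 1326 with the replicate number as a block. Without the block fewer arrays per group do not reach this, as 100 fits with 3 alone and 3 platelet exon arrays gave a median of 329.5 genes (179 to 960) and 0 gave 133 or fewer. With the block, 10 fits of 3 same-numbered exon pairs gave a median of 378 (7 to 993) and 6 gave 454 or fewer. Pairing by number is not established on the exon arrays, so these counts are not like the blocked gene-array count. The blocked fits cannot decide, and fewer arrays are not excluded. A narrower scale of the gene arrays could contribute: the slope of gene-array on exon-array level was 0.77. Scatter between the array types (r = 0.895) lowers such a regression slope, so it overstates a narrowing. The SD of the levels across genes was 2.63 on the exon and 2.27 on the gene arrays. Over the 559 genes past both controls the slope of the differences was 0.412. These genes were chosen on the exon arrays, which can enlarge their differences there. Over the 125 genes called on the gene arrays, the median sizes were 1.01 on the exon and 0.66 on the gene arrays. The test cannot tell. A weaker response in these cultures, or the other labelling kit, was not tested.

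Genes higher with platelets than alone on the exon arrays might reflect RNA that platelets bring. For 13 members of the platelet list, the difference between mixed at lysis and alone was a median share of 1.08 of the rise with platelets (quartiles 0.86 and 1.2), which fits that explanation, and 1.74 (1.41 and 1.94) within numbers 4 to 6, the only ones with mixed arrays, where the list rose by 0.75 against 1.73 in numbers 1 to 3. For the 381 other genes the median share was 0.04 (quartiles −0.09 and 0.2), or 0.03 within numbers 4 to 6, which excludes it for most of them, while 18 had a share of at least 0.75. Leukocytes carried along with the platelets stay open: between mixed at lysis and alone the mean of their list rose by 0.18 (exact two-sided permutation p = 0.0357) and the median was −0.01. The mean rested on 2 of 23 members, Laptm5 (3.27) and Fcer1g (1.14), the others had a mean of −0.012, and 17 members lay under the median of the arrays, where a small rise could be missed.

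Single arrays lay far from the others of their group by Dixon's test. In cells alone, Cdh1 was 11.10 in array 1 (nearest 10.36), Tgfb1 was 8.11 in array 5 (nearest 7.08), and the median of all probe sets was 3.9 in array 5 (nearest 3.7). With platelets, Ccl2 was 5.17 in array 4 (nearest 7.96), Ncam1 was 7.23 in array 4 (nearest 7.79), and Tgfb1 was 8.76 in array 5 (nearest 7.38). Of 96 groups of values tested, 6 gave such an array, and chance gives about 1 in 20 (4.8). Among 19477 exon-array probe sets without a gene symbol, which the comparisons did not use, 10 passed both controls (7 higher, 3 lower).

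Arrays were also split in other ways than by group, and the number of splits with at least as many genes as the real one was counted, with the real split included. For platelets against alone on the exon arrays, 2 of 100 reached the real count of 864. The highest other value, 994, came from a split near the sets of numbers. Within numbers 1 to 3 the real comparison gave 922 genes, and with the sets as a block 1076. The same block lowered the count against mixed at lysis from 699 to 551, and past both controls from 570 to 512. For platelets against mixed at lysis the number of splits was 1 of 56 (699, highest other 586), and past both controls 1 of 100 (570, highest other 13). For mixed at lysis against alone it was 3 of 56 (9, highest other 997, with alone 5 and mixed at lysis 5 and 6 on 1 side). That points to structure among the arrays, and chance is not excluded for that count.

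On the gene arrays, 3 against 3 arrays give only 10 splits, too few to exclude chance. It was 1 of 10 for platelets against alone (133, highest other 0, splits that part all same-numbered pairs included), 1 of 10 for pellet against alone (83, highest other 0) and 1 of 10 for platelets against releasate (9, highest other 1). It was 2 of 10 for pellet against releasate (1, highest other 1), and 10 of 10 for releasate against alone and for platelets against pellet (0, highest other 0). For the departure from the sum of pellet and releasate, all 100 of 100 splits reached the real count of 0. Every split reaches a real count of 0, here and in the 10 of 10 above, so these shares say nothing about chance. The highest other value was 355, in a redraw of the 4 groups with pellet 7, releasate 7 and releasate 9 as the platelet group. That points to structure among the arrays.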

How the results depend on the processing

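No called gene changed sign in any fit that left out 1 array, and the counts of 0 (releasate against alone, platelets against pellet, departure from the sum) stayed 0 under every setting. The cause was not tested for any of the moves below, except that a size limit lowers a count by construction.

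With an intensity trend and robust moderation, platelets against releasate gave 21 genes and pellet against releasate 16. Without dim genes, pellet against releasate gave 0 and the correlation of the array types was 0.696. With every named probe set, mixed at lysis against alone gave 14 and platelets against releasate 5. With equal array medians, platelets against releasate gave 5 and pellet against releasate 0. A log2 difference of at least 1 left 301 genes for exon platelets against alone, 313 against mixed at lysis, 231 past both, and on the gene arrays 30 for platelets, 18 for pellet, 2 for platelets against releasate and 0 for pellet against releasate. With only the compared groups, mixed at lysis against alone gave 18, gene-array platelets 80, pellet 34, and platelets against releasate 0.

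Outside the comparisons of gene-array alone, platelets and releasate, the pairing by replicate number is not established: arrays of the same number had correlations of −0.255 to 0.652 on the exon and −0.149 to 0.574 on the gene arrays. As a hint from the data, 7 of 12 exon and 11 of 12 gene-array samples with a partner correlated best with their own number. The block changed no call of the 3 paired comparisons beyond those given beside them. With the number as a block, exon platelets gave 1326 against alone, 472 against mixed at lysis and 461 past both. Mixed at lysis against alone gave 1. Gene-array platelets gave 454, pellet 359, platelets against releasate 98 and pellet against releasate 44. The proliferation list between mixed at lysis and alone reversed direction with the block, at an adjusted p of 0.74. Without the 2 arrays of conflicting tags, platelets gave 30, pellet 46, platelets against releasate 0 and pellet against releasate 0. With title serials as a block, pellet gave 51 and pellet against releasate 0. By the median over the list, platelet RNA in releasate against alone was 0.049. With mixed at lysis as the control, the correlation of the array types was 0.613.

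Of the settings chosen after seeing the data, array weights gave 1750 for exon platelets against alone, 4402 against mixed at lysis (2628 higher, 1774 lower), 231 for mixed at lysis against alone and 1244 past both. On the gene arrays they gave 464 for platelets, 501 for pellet, 42 for platelets against releasate and 37 for pellet against releasate. Only numbers 4 to 6 gave 42, 70, 3 and 40 for the exon counts in the same order. Without alone 1, alone 5, platelets 4 and platelets 5, platelets against mixed at lysis gave 2112 (1192 higher, 920 lower) and mixed at lysis against alone 16.

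Leaving out 1 array gave these ranges: exon platelets against alone 632 to 846, against mixed at lysis 397 to 756, past both 379 to 587, mixed at lysis against alone 1 to 7. On the gene arrays they were 21 to 119 for platelets, 8 to 133 for pellet, 4 to 12 for platelets against releasate and 0 for pellet against releasate. The correlation of the array types was 0.589 to 0.655, and platelet RNA in exon platelets against mixed at lysis −0.094 to 0.253. Of named genes, 84 of 115 exon and 6 of 45 gene-array calls held without each array, so the gene-array calls rest on few arrays. Values that never passed changed sign in 82 settings for named genes and 40 for lists.

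Under a scaling no list or named gene reversed, but calls were lost. With equal medians 4 list calls were lost: EMT transcription factors in exon platelets against alone (adjusted p = 0.0621), epithelial and cholesterol in platelets against pellet (0.0809 each), and YAP in the departure from the sum (0.0654). With quantile normalization 7 were lost: these last 3 (0.128, 0.128 and 0.0821), mesenchymal in pellet (0.0518), epithelial and proliferation in releasate (0.0574 and 0.0578) and ERK in the departure (0.07). The leukocyte list between mixed at lysis and alone then passed (0.0483). Named genes lost 18 calls with equal medians and 7 with quantile normalization. Those not given beside their genes are, with equal medians, Bnip3, Gsta4 and Nfkbia in exon platelets against mixed at lysis (0.0512, 0.109 and 0.0784), and with quantile normalization Bnip3, Pdk1 and Gsr in the latter (0.104, 0.09 and 0.073).

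With fry, 29 list calls were lost testing 1 direction and 23 testing either: 4 and 4 in mixed at lysis against alone, the others on the gene arrays. There, testing 1 direction, the platelet list alone kept its calls and every other list call was lost (adjusted p = 0.116 to 0.929). In the exon cultures 0 were lost, and testing 1 direction 6 came to pass: matrix proteolysis and mammary against alone (0.000907 and 0.00202), and EMT transcription factors, NF-kappaB, matrix proteolysis and YAP against mixed at lysis (0.00154, 0.00538, 0.027 and 0.000742). Testing either direction, 16 came to pass over both array types. Fry does not compare a list with other genes, so such a loss or gain answers another question than camera.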

Other observations

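Both tests of this part were chosen only after the result was seen. The 559 genes past both controls on the exon arrays were followed on the gene arrays as a signed mean, counting exon-higher genes up and exon-lower genes down. It was 0.46 ± 0.088 (SD, n = 3) with platelets, 0.408 ± 0.09 with pellet, 0.119 ± 0.079 with releasate and 0 ± 0.037 alone. The response may follow the pellet more than the releasate, and the difference of 0.29 between them fits that. By camera with an estimated correlation, the 236 exon-higher genes were higher with pellet than with releasate (p = 0.00311) and the 323 exon-lower genes lower (p = 0.00333). Whether the releasate alone moves the same genes stays open at a signed mean of 0.119. For it, the releasate array was above the alone array of its number in each case (0.038 and −0.023, 0.121 and 0.042, 0.196 and −0.019), by 0.061, 0.079 and 0.215, 463 of 559 genes (82.8%) had the exon direction, and the exon-lower genes were lower by camera with an estimated correlation (p = 0.0216, and 0.0121 with the replicate number as a block). Against it, the exon-higher genes missed the threshold by camera with an estimated correlation (p = 0.185, and 0.143 with the block). An exact two-sided permutation test of the signs of the 3 differences gave p = 0.25, the smallest that 3 pairs allow.

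Vim on the gene arrays was 8.99, 10.31 and 7.90 in alone 7, 8 and 9, and 9.90, 10.85 and 9.24 with platelets in the same order. Of the 177 genes that differed between exon arrays numbered 1 to 3 and 4 to 5, 120 were higher and 57 lower in the first set. Those with large differences, chosen after their values were seen, include Trpa1 (2.95), Itm2a (2.84), Casp12 (2.04), Egln3 (−2.44) and Dsc2 (−1.41).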
